A study of Clostridium acetobutylicum with 12 samples.

How the data were processed

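RNA of 2 strains of the anaerobic, solvent-producing bacterium Clostridium acetobutylicum was compared on 12 two-colour arrays, 4 on each of 3 platforms. Strain ATCC824 is the type strain, and M5 is a degenerate strain that lacks the pSOL1 megaplasmid and no longer makes solvents. Per the labels, RNA from several exponential-phase samples was mixed within each strain. The ATCC824 mixture held 4 samples taken at optical densities of 1.09 to 2.6. The M5 mixture held 6 samples from 0.454 to 4.2, except that the labels of the ChIP-capable arrays S2 and S4 list 5 samples, from 0.868 on. The amount of labelled material was 0.75 micrograms. On arrays S1 and S3 of each platform M5 carried Cy3 and ATCC824 carried Cy5, and on S2 and S4 the dyes were swapped. The 2 ChIP-capable arrays with the shorter list are also that platform's arrays with M5 in Cy5, so the mixture and the dye cannot be separated there.

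The first platform was an Agilent 60-mer array designed for transcription, the second an Agilent 60-mer array that the labels call capable of ChIP-on-chip, and the third a spotted array. The deposited scanner files of the 60-mer platforms came from Agilent Feature Extraction 8.5 and those of the spotted platform from GenePix Pro 5.1.0.19, per the file headers and the submitters' processing notes. Per the file headers, these deposited files hold an intensity per spot and channel, as mean foreground and local background, neither of them normalized. The Agilent files also hold a processed intensity that, per the file headers, the scanner software had background-subtracted and dye-normalized, a log10 ratio of red over green made from it, and 0 or 1 marks for spots well above background, saturated or non-uniform. The GenePix files hold a spot mark set in the scanner software, which was not used here.

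A second set of deposited tables holds the authors' processed value per spot. Their scale was found by setting them against the scanner ratios of bright spots. The absolute slopes on log2 ratios were 0.683 to 0.720, which is the natural log, and the sign changed with the dye swap in the way a ratio of ATCC824 over M5 would. Ratios here run the other way, as M5 over ATCC824. The medians of the deposited natural log columns for S1 to S4 were 0.0388, 0.0343, 0.0349 and 0.0170 on the transcriptional platform. They were 0.0589, 0.0636, 0.0350 and 0.0590 on the ChIP-capable platform, and 0.0615, 0.0487, 0.0607 and 0.0260 on the spotted platform. How the authors normalized, filtered and centred these deposited values is not given in the sources used here.

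The main values were computed from the scanner intensities with limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table for reading. Background was corrected with the normexp method at an offset of 50, which pulls the ratios of dim spots towards 0. A loess curve (span 0.3, 4 iterations) was then fitted within each array, with control spots and spots marked as outliers at weight 0. Those spots were left out afterwards, and saturated spots were kept. Swapped arrays were turned so that every log2 ratio is M5 over ATCC824. Spots of 1 probe were averaged, and a gene's value was the median over its probes. A sequence listed under 2 genes was used for neither. Genes are named by the loci, symbols and descriptions in the files, in which CAP marks pSOL1 and CAC the chromosome. For well-known loci the usual symbol is printed. No genome sequence was used here, so no coordinates are given.

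A gene counted as measured on a platform when 1 of its probes was well above background in 1 strain on all 4 arrays and the gene had a value on all 4. The Agilent software marks such spots with a limit of 2.6 background SDs, and the same multiplier was applied to the spotted arrays. Outlier marks removed 10.1% of gene spots on the transcriptional platform and 5.22% on the ChIP-capable platform. On the spotted platform 4.29% were not used, because no intensity was given for them on an array. Array S2 of the transcriptional platform lost 4665 spots. Some genes named from 1 platform were lost from the others in this way. Where a gene's M5 signal was not well above background on any array of a platform, its fold is given as a lower bound. The bound sets the mean normalized ATCC824 level against the M5 floor, which on each array was the higher of the gene's own level and the lowest level well above background. For such a gene the mean log2 ratio and its SD are taken over the other platforms. A saturated spot clips its channel, so the text says where a named gene had a probe saturated on all 4 arrays of a platform.

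The labels describe mixtures of RNA samples and name no separate cultures per array, so arrays are treated as technical repeats, and no p-value is given for the difference between strains. Whether the 2 ChIP-capable arrays with the shorter list carried another M5 mixture is not settled by the labels. A gene was called higher or lower in M5 by size, with a mean change of at least 2-fold and the same sign on all 4 arrays. In the counts of gene list members, a gene counted as called only when every platform that measured it called it alike. Platforms were compared with the array as the unit. The median pSOL1 ratio was compared with an exact two-sided permutation test. Single genes were compared with limma's moderated test over all 12 arrays, with a dye term for each platform, Benjamini-Hochberg adjustment over the 3086 genes measured on every platform, and a difference of at least 2-fold. These p-values measure only the spread between arrays, which is technical. Each gene list was described by the median of its members' mean log2 ratios over platforms and by the percentile of that median among 10000 random lists of the same size matched on brightness. Random lists for the lists of pSOL1 genes were drawn from all measured genes, and those for every other list from chromosomal genes alone. The ranges given with the lists run from percentile 2.5 to 97.5 of those random lists.

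The genes named were set by rule. The rule took all members of the lists of solvent formation and of acid formation genes, and the 10 highest and 10 lowest chromosomal genes called alike on every platform that measured them, with at least 2 platforms. It also took the 3 lowest and up to 5 highest pSOL1 genes, and up to 4 called members of each list with the largest changes. This rule, the lists, the tests and most alternatives were fixed before the data were examined. The alternatives tried were the scanner software's own signals, an offset of 10, median centring, loess on chromosomal spots, the deposited natural log values, the brightest probe, no filter on dim genes and leaving out each array. Thresholds of 1.5-fold and 3-fold, limma calls against array spread, rank correlation, chromosomal genes alone, each platform alone, and blocks for array number and scan day were also run. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.

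The calculations were tested on simulated data. For M5 over ATCC824, 50 genes were changed at each size among 3804 genes on the transcriptional, 3827 on the ChIP-capable and 3188 on the spotted platform. The changed genes were drawn only from genes at or above their platform's median brightness. The size rule's rates and fold estimates below therefore do not cover dimmer genes. The size rule called 0% of genes changed 1.5-fold on each platform, and 100% of those changed 4-fold or 8-fold. Genes changed exactly 2-fold were called in 10% of cases on the transcriptional, 18% on the ChIP-capable and 38% on the spotted platform, and 0 unchanged genes were called. An 8-fold change was estimated at a median of 6.96-fold, 7.09-fold and 7.54-fold on the respective platforms, so large changes come out too small. For the difference between the spotted and the transcriptional platform, tested on 3000 genes, 0% of 1.5-fold, 42% of 2-fold and 100% of 3-fold and 4-fold differences were called. For the gene list medians, 3 of 100 lists without a shift and 20 of 20 lists shifted by 1 log2 unit fell outside the middle range. The simulated genes were independent of each other and the lists were not matched on brightness. This test therefore does not cover lists of adjacent loci, whose ratios were alike.

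Precision is limited by the 4 arrays per platform and by signal over background. The median of the SD over 4 arrays of a gene's log2 ratio was 0.0919 on the transcriptional, 0.0842 on the ChIP-capable and 0.0809 on the spotted platform. On the 60-mer platforms the probes of a gene disagreed in few cases. Of 3456 transcriptional genes with several probes, 88 had probes over 2-fold apart, as had 81 of 3735 ChIP-capable genes, and 1 and 0 genes had probes 2-fold in opposite directions. Array numbers S1 to S4 were tested as a pairing across platforms and were not used as one. The scan days in the file headers put S1 and S2 of both 60-mer platforms on 1 day and S3 and S4 on another. The spotted arrays were scanned together on a day of their own, so for them day and platform cannot be told apart.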

Results

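Transcript levels of Clostridium acetobutylicum M5, a degenerate strain without the pSOL1 megaplasmid, were compared with those of the type strain ATCC824 on 12 two-colour arrays. The arrays fell into 3 groups of 4 by platform, named here the transcriptional 60-mer, the ChIP-capable 60-mer and the spotted platform. Per the labels each array carried a mixture of exponential-phase RNA samples of each strain, with the dyes swapped on arrays S2 and S4. The mixtures covered different growth ranges, with optical densities of 1.09 to 2.6 for ATCC824 and 0.454 to 4.2 for M5, except that ChIP-capable arrays S2 and S4 list M5 samples from 0.868 on, so strain and sampling range were not separable. The 60-mer platforms each had 22575 spots per array and 3916 genes, and the spotted platform had 12342 spots and 3778 genes. The median spot signal above background on the 60-mer arrays was 205.5 to 373 in the M5 channel and 166 to 293 in the ATCC824 channel, over median backgrounds of 23 to 41. On the spotted arrays it was 436 to 921 for M5 and 282 to 552 for ATCC824, over backgrounds of 80 to 231. Gene spots were well above background in 89.1% to 96.3% of cases on the 60-mer arrays and in 78.4% to 89.6% on the spotted arrays, counted per array and channel. In M5, 3674 (transcriptional) and 3693 (ChIP-capable) of 3738 chromosomal genes passed this mark on all 4 arrays. Fewer, 3271 and 2663, exceeded the 95th percentile of the negative control spots on all 4. The mark is thus a loose limit on the 60-mer arrays. By the rule for measured genes, 3804 genes were measured on the transcriptional, 3827 on the ChIP-capable and 3188 on the spotted platform. Arrays of 1 platform correlated across genes with r of 0.975 to 0.985 (transcriptional), 0.976 to 0.993 (ChIP-capable) and 0.973 to 0.993 (spotted). Genes are not independent replicates in such a correlation. Below, ratios are M5 over ATCC824, which is opposite to the direction of the authors' deposited values, and the error after a gene's mean log2 ratio is the SD of the 3 platform means unless stated otherwise. The error after a list median is the SD between arrays of a platform, pooled over platforms.

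The first comparison asked how far the genes of pSOL1, for which M5 has no template, fell below ATCC824. All 6 solvent formation genes of pSOL1 were lower in M5 on every platform, with a median log2 ratio of -5.70 ± 0.39 (52.0-fold lower). This size depends on the processing, since the median was -6.87 at an offset of 10, -7.43 with the scanner software's signals and -8.12 with the deposited values. The lowest was adc (CAP0165), encoding acetoacetate decarboxylase, the last enzyme of acetone formation. It was 642-fold lower on the transcriptional and 730-fold lower on the ChIP-capable platform, and at least 732-fold lower on the spotted platform, where its M5 signal was not well above background. On the ChIP-capable platform it was well above background on 3 of 4 arrays. With no template in M5 and M5 levels near the added offset of 50, these folds depend on the offset. The aldehyde-alcohol dehydrogenase gene adhE1 (CAP0162) had a log2 ratio of -6.90 ± 0.52 (120-fold lower). The genes of the CoA-transferase that feeds acetone formation, ctfA (CAP0163) and ctfB (CAP0164), had -5.68 ± 1.01 and -5.72 ± 1.34. On the spotted platform ctfA was well above background in M5 on 1 of 4 arrays, and ctfB and adhE1 on 3 of 4. The pyruvate decarboxylase gene pdc (CAP0025) had -4.60 ± 0.24 on the 60-mer platforms (SD of the 2 platform means) and was at least 45.5-fold lower on the spotted platform. The second aldehyde-alcohol dehydrogenase gene, adhE2 (CAP0035), had -4.00 ± 1.32, with -2.98 ± 0.66 on the transcriptional, -5.49 ± 0.31 on the ChIP-capable and -3.51 ± 0.13 on the spotted platform (SD, n = 4 arrays each).

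Outside solvent formation, the regulator gene thlR (CAP0079) had a log2 ratio of -6.59 ± 0.14 on the 60-mer platforms (SD of the 2 platform means) and was at least 27.97-fold lower on the spotted platform. CAP0066 and CAP0067, annotated as components of a mannose-type phosphotransferase system, had -5.86 ± 0.83 and -5.80 ± 1.04. CAP0068, of the same system, had -4.96 ± 0.48 on the 60-mer platforms and was at least 52.0-fold lower on the spotted platform. The 60-mer M5 levels of thlR and of CAP0066 to CAP0068 lay near the added offset, so the sizes of their ratios depend on it. At the other end were pSOL1 genes whose signals differed little between the strains. M5 has no template for them, so their M5 signal does not measure their transcripts. CAP0022, annotated as a spore germination protein, had 0.01 ± 0.41, which was -0.30 ± 0.07 on the transcriptional, -0.14 ± 0.03 on the ChIP-capable and 0.48 ± 0.03 on the spotted platform (SD, n = 4). Its mean log2 levels in M5 and ATCC824 were 11.4 and 10.9 on the spotted platform. They were 6.04 and 6.34 on the transcriptional and 6.17 and 6.33 on the ChIP-capable platform. The source of the spotted signal was not tested. CAP0145 had -0.07 ± 0.12, and CAP0143, a predicted hydrogenase maturation protease measured on the 60-mer platforms, had -0.12 ± 0.02 (SD of the 2 platform means). CAP0155, measured on the spotted platform only, had 0.15 ± 0.05, and CAP0170, measured on the ChIP-capable platform only, had -0.12 ± 0.09 (SD, n = 4 arrays each). The ATCC824 levels of CAP0145, CAP0143 and CAP0170 on the 60-mer platforms that measured them were also near the offset, at 6.19 to 6.44. Their ratios there therefore rest on little signal in either strain. The signs of CAP0022 and CAP0155 changed with the processing. A 60-mer probe shared by both designs shows the range. The adc probe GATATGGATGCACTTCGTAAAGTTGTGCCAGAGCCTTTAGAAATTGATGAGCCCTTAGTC, with a GC content of 43.3%, gave -9.74 ± 0.27 and -9.58 ± 0.18 on the transcriptional and ChIP-capable platforms. The CAP0022 probe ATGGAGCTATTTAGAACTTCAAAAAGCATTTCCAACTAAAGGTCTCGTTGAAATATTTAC, with a GC content of 31.7%, gave -0.24 ± 0.12 and -0.18 ± 0.08 (SD, n = 4).

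Over all measured pSOL1 genes the median log2 ratio was -0.96 ± 0.19 on the transcriptional, -0.80 ± 0.11 on the ChIP-capable and -1.73 ± 0.18 on the spotted platform (SD, n = 4 arrays each). These are medians of 1.95-fold, 1.74-fold and 3.31-fold lower. The rule for a 2-fold change called 85 of 171 pSOL1 genes lower on the transcriptional, 73 of 169 on the ChIP-capable and 99 of 131 on the spotted platform, and 0 higher on each. On the spotted platform 35 of these 131 genes had a bound only, and with them at their bound the median was -1.67 and 99 genes were again lower. On all 3 platforms 59 pSOL1 genes were lower. Over the platforms that measured each gene, 64 of 175 were lower on every one, the list median was -1.07 ± 0.16, and it lay at percentile 0 of matched random lists (-0.07 to 0.02). Among pSOL1 genes on the platform, the M5 signal was well above background on all 4 arrays for 115 of 178 on the transcriptional, 119 of 178 on the ChIP-capable and 59 of 172 on the spotted platform. It was so on 0 arrays for 0, 0 and 59 genes respectively. These marks compare a spot with background. Against the negative control spots of the 60-mer arrays, 15 and 2 of 178 genes exceeded the 95th percentile in M5 on all 4 arrays. The medians depend on the processing, and with the scanner software's signals they were -2.97 and -2.58 on the 60-mer platforms.

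**Figure D1:**
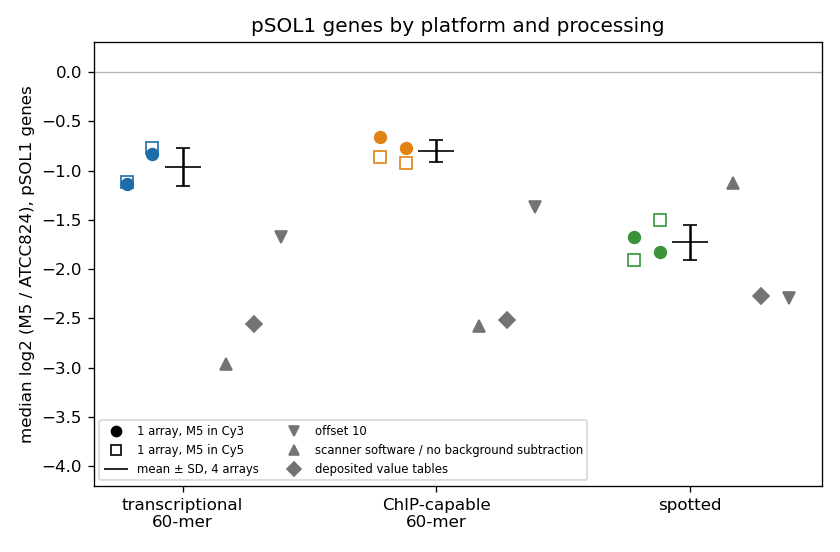
Median log2 ratio of M5 over ATCC824 across measured pSOL1 genes, per array (points), with mean and SD over 4 arrays, for each platform and processing. In the main processing the spotted arrays lie between -1.50 and -1.91 and the 60-mer arrays between -0.66 and -1.13, whereas with the scanner software's signals the 60-mer means lie at -2.97 and -2.58.

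The second comparison concerned chromosomal genes. The largest increases in M5 were in branched-chain amino acid synthesis, where leuC (CAC3173), a subunit of isopropylmalate dehydratase, had a log2 ratio of 4.67 ± 0.22 (25.5-fold higher). The acetolactate synthase gene ilvB (CAC3169) had 4.56 ± 0.31 (23.6-fold), the isopropylmalate dehydrogenase gene leuB (CAC3171) had 4.36 ± 0.68 (20.6-fold), and the dihydroxyacid dehydratase gene ilvD (CAC3604) had 3.99 ± 0.41 (15.9-fold). On the spotted platform the ATCC824 signal was well above background on 1 of 4 arrays for leuC, 2 for ilvD and 3 for leuB, so their sizes there lean on dim signals. Next came the purine synthesis genes purM (CAC1393) at 3.98 ± 0.18 and purE (CAC1390) at 3.69 ± 0.12, and purN (CAC1394) at 3.94 ± 0.38 over the 2 platforms that measured it. The gluconate permease gene gntP (CAC2835) had 3.72 ± 0.18, the hypothetical gene CAC1073 had 3.69 ± 0.38, and CAC0658, an annotated Fe-S oxidoreductase measured on 2 platforms, had 3.69 ± 0.24. On the spotted platform CAC0658 was too dim to count as measured. Its mean log2 levels there were 6.40 in M5 and 6.78 in ATCC824, so the rise was not seen on that platform. For gntP the ATCC824 signal was well above background on 2 of 4 spotted arrays.

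The largest decreases in M5 were in CAC0588, a hypothetical gene, at -5.64 ± 0.38 (50.0-fold lower) and in its neighbour CAC0587, annotated as a flavodoxin. CAC0587 had -5.39 ± 0.25 on the transcriptional, -5.67 ± 0.10 on the ChIP-capable and -4.66 ± 0.41 on the spotted platform (SD, n = 4). Its ATCC824 spots were saturated in 19 of 24 and 9 of 24 readings on the 60-mer platforms, with 1 of 3 probes saturated on all arrays of each, so its size there is uncertain. A block of ferrichrome transport genes was lower, with fhuD (CAC0790) at -4.35 ± 0.21 (20.3-fold lower), CAC0788 at -4.23 ± 0.15, fhuB (CAC0789) at -4.06 ± 0.97 and fhuC (CAC0791) at -3.98 ± 0.32. Beside them lay CAC0787, a conserved protein measured on 2 platforms, at -4.06 ± 0.57. CAC1590, annotated as a 2-oxoglutarate/malate translocator, had -4.21 ± 0.03 on the 60-mer platforms (SD of the 2 platform means) and was at least 15.4-fold lower on the spotted platform. On each 60-mer platform its M5 signal was well above background on 3 of 4 arrays. Its M5 levels there lay near the added offset, so its size is uncertain. CAC1471, annotated as ketopantoate reductase, had -3.97 ± 0.33, and the probable S-layer protein gene CAC3556 had -3.79 ± 0.17.

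**Figure D2:**
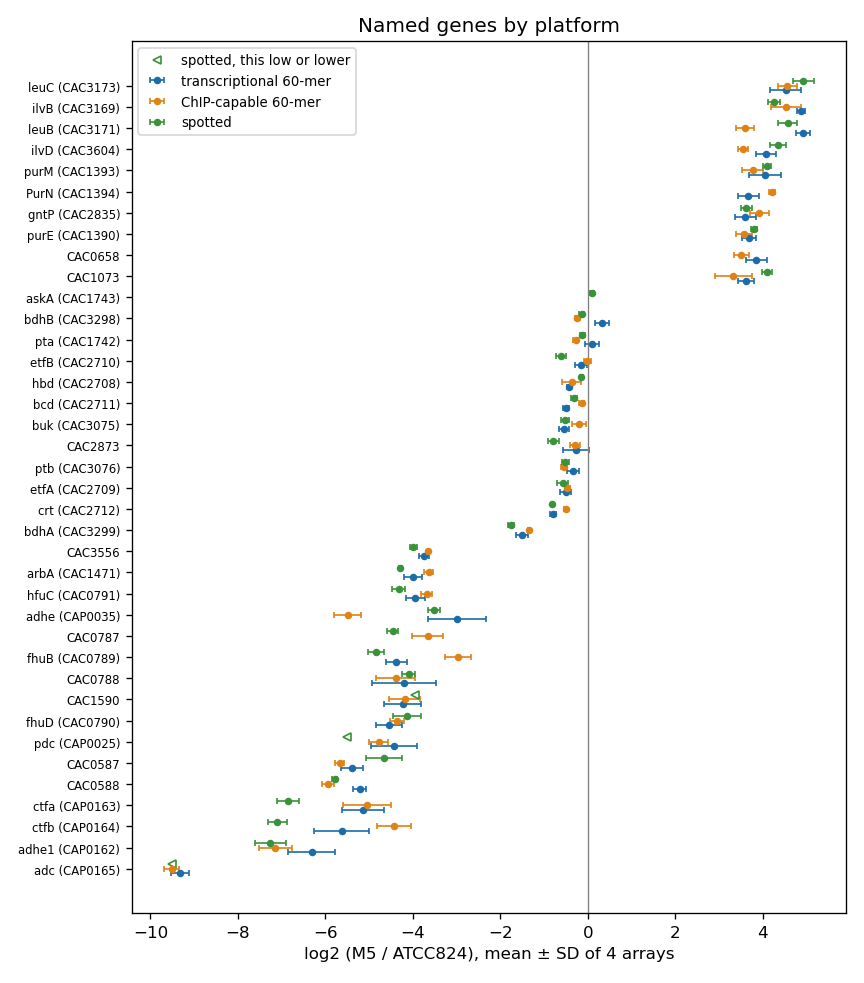
Log2 ratio of M5 over ATCC824 for the named genes on each platform, as mean and SD of 4 arrays, with 1 colour per platform. Open triangles mark bounds on the spotted platform, where the true ratio is this low or lower. The genes run from adc, below -9 on every platform, to leuC, between 4.53 and 4.93.

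In all, 325 chromosomal genes were higher and 196 lower in M5 on the transcriptional platform, out of 3633 measured. On the ChIP-capable platform 293 were higher and 186 lower out of 3658, and on the spotted platform 379 and 214 out of 3057. On all 3 platforms 213 genes were higher and 128 lower, of the 2961 chromosomal genes measured on each. Requiring a limma adjusted p under 0.05 against the spread between arrays, besides the 2-fold change, gave the same counts. With arrays centred on their medians in place of the loess curve, the counts became 516 higher and 121 lower, 464 and 110, and 488 and 159 on the respective platforms. The share of calls that were higher then moved from 62.4%, 61.2% and 63.9% to 81.0%, 80.8% and 75.4%, and the median chromosomal log2 ratio on the spotted platform became 0.11.

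Counts of list members below are of genes called alike on every platform that measured them, and single platforms can call further members. Among gene groups, the list of branched-chain amino acid synthesis held the 6 genes of 1 cluster (CAC3169 to CAC3174). All 6 were higher in M5 on every platform that measured them, with a median log2 ratio of 4.46 ± 0.23 (22.01-fold). The list leaves out ilvD (CAC3604) at 3.99 and ilvN (CAC3176) at 1.52, which were also higher. Here ilvN was named after its value was seen. Random matched lists ranged from -0.56 to 0.95, which put the median at percentile 100. The ilvD copy of this cluster, CAC3170, was measured on the spotted platform only, at 4.58 ± 0.12 (SD, n = 4). Of 11 purine synthesis genes 8 were higher and 0 lower, with a median of 3.46 ± 0.17 (11.0-fold, percentile 100), and among them purF (CAC1392), measured on the spotted platform only, had 3.78 ± 0.10 (SD, n = 4). All 7 pyrimidine synthesis genes were higher, with a median of 2.51 ± 0.21 (5.71-fold, percentile 100). Examples are carB (CAC2644) at 3.05 ± 0.19, carA (CAC2645) at 2.69 ± 0.56, pyrI (CAC2653) at 2.63 ± 0.13 and pyrD (CAC2650) at 2.51 ± 0.33. For pyrI the ATCC824 signal was well above background on 2 of 4 spotted arrays. The lists of histidine and tryptophan synthesis did not share this rise. The 9 histidine synthesis genes had a median of -0.46 ± 0.08 (percentile 0.23) and the 7 tryptophan synthesis genes 0.0039 ± 0.066 (percentile 56.5). In both lists 0 members were called alike on every platform that measured them, while 1 histidine gene was higher on the spotted platform. The size of the histidine median depends on the processing. It was -0.78 with the scanner software's signals, -0.89 with the deposited values and -0.11 on the spotted platform alone.

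Ribosomal protein genes were higher as a group. Of 63 genes whose annotation names a ribosomal protein 28 were higher, 1 was lower and 34 were neither, with a median of 1.04 ± 0.06 (2.05-fold, percentile 100, random range -0.20 to 0.30). Without 4 of them that are annotated as other proteins (CAC0152, CAC0715, CAC1801 and CAC3423), 26 of 59 were higher and the median was again 1.04. Examples are CAC3141 at 1.77 ± 0.06 and rplD (CAC3132) at 1.55 ± 0.12. The L11 gene rplK (CAC3148) had 1.66 ± 0.97, with 1.10 on both 60-mer platforms and 2.78 on the spotted platform. The member that was lower, rpsD (CAC1478), at -1.39, was named after its value was seen. Of 27 aminoacyl-tRNA synthetase genes 4 were higher and 0 lower, with a median of 0.20 ± 0.04 (percentile 82.1). These 4 were serS (CAC0017) at 2.87 ± 0.28, leuS (CAC0646) at 2.32 ± 0.13, metS (CAC2991) at 2.27 ± 0.29 and aspS (CAC2269) at 1.20 ± 0.05. The 8 ATP synthase genes had a median of 0.46 ± 0.07 (percentile 81.3), with 0 called.

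In central metabolism, 4 of 10 glycolysis genes were lower in M5 and 0 higher, with a median of -1.08 ± 0.08 (2.12-fold lower, percentile 0.07). They were eno (CAC0713) at -2.43 ± 0.17, pgm (CAC0712) at -1.92 ± 0.20, tpi (CAC0711) at -1.70 ± 0.12 and gapC (CAC0709) at -1.35 ± 0.13. For gapC 1 of 3 probes on the transcriptional platform was saturated in ATCC824 on all arrays, so its size there is uncertain. The median was -0.50 with median centring. Of the 12 genes of chromosomal acid formation and butanol dehydrogenases 1 was lower. It was bdhA (CAC3299), a butanol dehydrogenase gene, at -1.53 ± 0.21 (2.90-fold lower). The list median was -0.37 ± 0.06 (percentile 7.18, random range -0.52 to 0.76). With median centring it was 0.25 (percentile 17.4, random range -0.07 to 1.24), so the random lists moved up as well and the list lay within their range both times. In butyryl-CoA formation thlA (CAC2873) had -0.44 ± 0.30, crt (CAC2712) -0.70 ± 0.17, hbd (CAC2708) -0.31 ± 0.15, bcd (CAC2711) -0.32 ± 0.18, etfB (CAC2710) -0.25 ± 0.31 and etfA (CAC2709) -0.51 ± 0.05. Of the genes that release butyrate and acetate, ptb (CAC3076) had -0.46 ± 0.12, buk (CAC3075) -0.42 ± 0.19, pta (CAC1742) -0.10 ± 0.18 and the acetate kinase gene CAC1743, on the spotted platform only, 0.10 ± 0.04 (SD, n = 4). The second butanol dehydrogenase gene, bdhB (CAC3298), had -0.02 ± 0.30. Of 4 genes for pyruvate oxidation and hydrogen evolution 1 was higher, the hydrogenase gene hydA (CAC0028) at 1.46 ± 0.27 (2.76-fold), and the list median of 0.17 ± 0.14 lay at percentile 65.3. That median was -0.0903 with the scanner software's signals, so its sign is not settled.

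Some genes of motility, sugar phosphotransferase systems and phage regions were lower. Of 99 flagellar and chemotaxis genes 7 were lower and 0 higher, with a median of -0.17 ± 0.03 (percentile 0.04). They included the flagellin gene CAC1634 at -2.84 ± 0.38, motB (CAC0305) at -1.38 ± 0.02 and the cheX gene CAC0586 at -1.34 ± 0.31. The flagellin gene hag (CAC2203) had -2.45 ± 0.12, with ATCC824 spots saturated in 12 of 20 and 12 of 24 readings on the transcriptional and ChIP-capable platforms and 1 of 3 probes saturated on all arrays of each. Of 165 genes in the annotated prophage regions 26 were lower and 0 higher, with a median of -0.19 ± 0.05 (percentile 0). The prophage median was -0.038 (percentile 0.05) with median centring, -0.25 with the scanner software's signals and -0.33 with the deposited values. Examples are CAC1886 at -1.82 ± 0.21, CAC1913 at -1.75 ± 0.10, CAC1878 at -1.67 ± 0.17 and CAC1892 at -1.65 ± 0.13. Of 32 sugar phosphotransferase genes 4 were lower, with a median of -0.18 ± 0.08 (percentile 0.12). Of these 4, CAP0066, CAP0067 and CAP0068 lie on pSOL1, and the other was licB (CAC0384) at -1.21 ± 0.01. Random lists for this list held chromosomal genes alone, so its pSOL1 members can lower the percentile. The list median was -0.30 with median centring, -0.39 with the scanner software's signals and -0.54 with the deposited values. Of 18 iron transport genes 8 were lower and 2 higher. Besides the ferrichrome genes, the ferrous iron transport genes feoB (CAC1031), at -2.92, and CAC0448, at -2.04, were lower, whereas CAC1989, at 1.57, and CAC2441, at 1.40, were higher. These 4 were named after their values were seen. The iron list's median was -0.45 ± 0.08 (percentile 0.52) and turned to 0.05 (percentile 8.90) with median centring.

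Sporulation, chaperone and cellulosome genes showed few calls. Of 89 sporulation genes 3 were higher and 2 lower, with a median of -0.09 ± 0.04 (percentile 1.0, against 4.90 with median centring, 4.45 with the scanner software's signals and 5.60 with the deposited values). This list holds pSOL1 genes such as CAP0091, while its random lists held chromosomal genes alone, which can lower its percentile. The anti-sigma factor gene spoIIAB (CAC2307) had 1.62 ± 0.02 and the sigma factor F gene (CAC2306) 1.42 ± 0.20. CAC3649, a possible spoVT, had -1.30 ± 0.14 over 2 platforms, and CAP0091, a predicted regulator of sporulation genes on pSOL1, had -2.85 ± 0.54 on the 60-mer platforms (SD of the 2 platform means) and was at least 11.1-fold lower on the spotted platform. Of 15 heat shock and chaperone genes 1 was called on every platform that measured it. It was clpC (CAC3189), measured on the spotted platform only, at 1.04 ± 0.08 (SD, n = 4). On single platforms, 1 other member was higher on the transcriptional and 2 on the ChIP-capable platform. On the 60-mer platforms clpC did not meet the rule for measured genes, although both strains were well above background on all 4 arrays. Its mean log2 levels there were 14.04 in M5 against 13.54 in ATCC824 (transcriptional) and 14.01 against 13.72 (ChIP-capable). These levels were under 2-fold apart. The list median was 0.38 ± 0.11 (percentile 83.0). The 10 cellulosome genes had a median of 0.12 ± 0.04 (percentile 88.1). Of them 0 were called on every platform that measured them, and 1 was higher on the spotted platform. Percentiles describe these mixtures and are not tests of the strains. Random lists hold scattered genes, while several lists hold adjacent loci, whose log2 ratios correlated at 0.610. The percentiles of such lists can therefore look more extreme than they are.

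**Figure D3:**
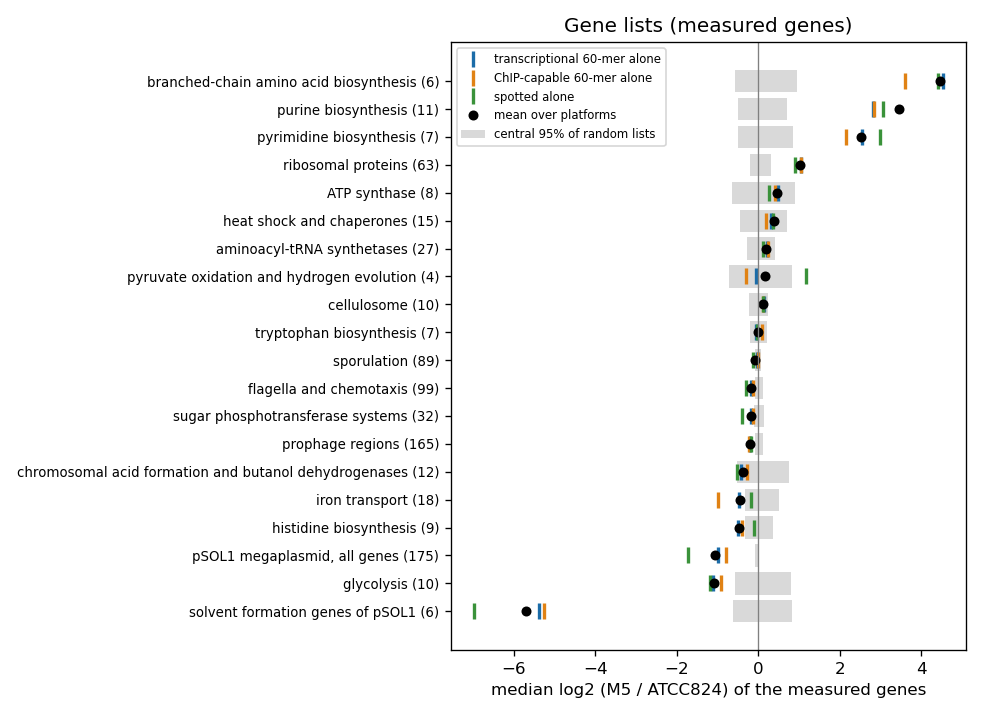
Median log2 ratio of M5 over ATCC824 for each gene list, with the number of measured genes in parentheses. Black points are the values over platforms, coloured ticks each platform alone, and grey bars the middle 95% of random matched lists. Branched-chain amino acid, purine and pyrimidine synthesis lie at 4.46, 3.46 and 2.51, and the solvent formation genes at -5.70.

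The third comparison asked how far the platforms gave the same ratios. The 60-mer platforms correlated across 3746 genes with r = 0.969 (Spearman's rho 0.950). The spotted platform correlated with the transcriptional platform at r = 0.904 (rho 0.864, 3116 genes) and with the ChIP-capable platform at r = 0.890 (rho 0.840, 3142 genes). Of the named genes, adhE2 was 2.51 log2 units higher on the transcriptional than on the ChIP-capable platform, leuB was 1.32 higher, and ctfB and fhuB were lower there, with differences of -1.19 and -1.41. The M5 levels of adhE2 and ctfB on the 60-mer platforms lay near the added offset, so the sizes of their differences are uncertain. The larger gap between the designs was in their ATCC824 levels. For adhE2 these were 8.96 (transcriptional) and 11.3 (ChIP-capable), with M5 at 5.89 and 5.94. For ctfB they were 11.3 and 10.6, with M5 at 5.80 and 5.94. Against the spotted platform, ctfB was 1.48 higher on the transcriptional and 2.67 higher on the ChIP-capable platform, and rplK was lower on both 60-mer platforms, with differences of -1.68 and -1.69. In 2 genes the calls were opposite. CAC0661, an annotated ABC transporter component, had 1.96 and 1.92 on the 60-mer platforms and -1.07 on the spotted platform, and cbiG (CAC1370), of cobalamin synthesis, had 1.07, 1.13 and -1.02. These 2 genes were named after their values were seen.

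**Figure D4:**
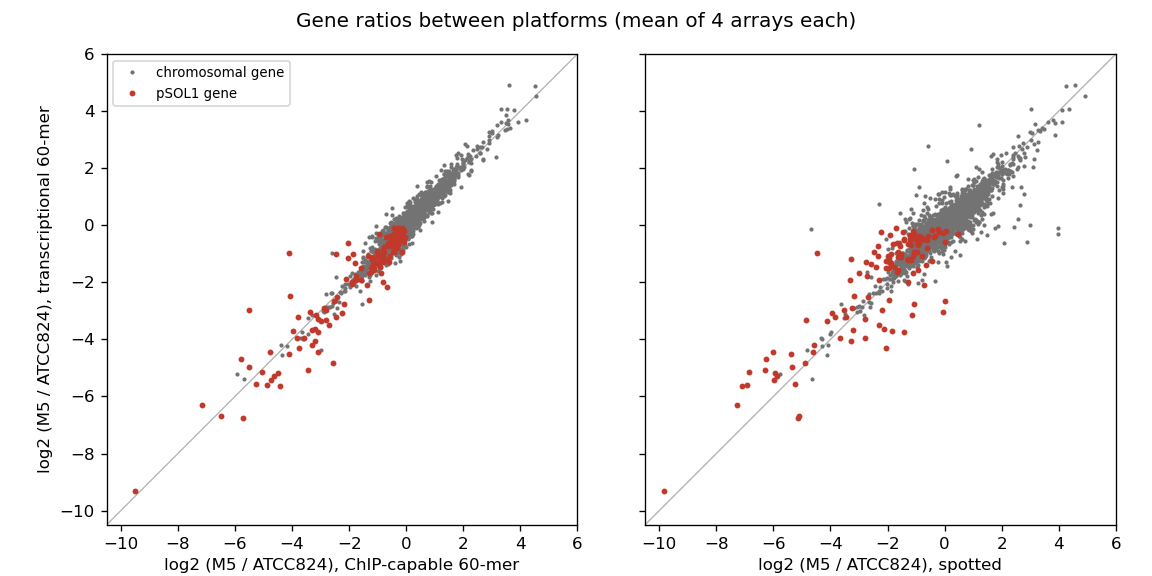
Mean log2 ratio of M5 over ATCC824 per gene on the transcriptional platform (vertical axis) against the ChIP-capable and the spotted platform (horizontal axes). Each point is 1 gene, with pSOL1 genes in red and the line of equal values in grey. The correlations were 0.969 with the ChIP-capable and 0.904 with the spotted platform.

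By limma (adjusted p under 0.05, at least 2-fold apart), 20 of 3086 genes differed between the 60-mer platforms, of which 12 were pSOL1 genes. Between the transcriptional and the spotted platform 125 genes differed, 34 of them from pSOL1, and between the ChIP-capable and the spotted platform 147, 46 of them from pSOL1. Both strains were above background on at least 1 array of each platform for 113 of the 125 and 123 of the 147, while the others rest on a bound, and in 2 genes of each comparison the bound leaves the direction open. The pSOL1 median was 0.76 log2 units higher on the transcriptional than on the spotted platform and 0.93 higher on the ChIP-capable than on the spotted platform. Each gave an exact two-sided permutation p of 0.0286, the smallest that 4 arrays against 4 allow, and an adjusted p of 0.0429 over 3 comparisons, and every 60-mer array lay above every spotted array. These medians cover different pSOL1 genes on each platform. Over the 125 pSOL1 genes measured on all platforms the differences were 0.48 and 0.66 and did not pass the threshold (adjusted exact p 0.0857 each). The 60-mer platforms differed by -0.16 (exact permutation p = 0.229, adjusted p 0.229). Within scan days that difference was 0.042 on the day of S3 and S4 and -0.37 on the day of S1 and S2, while 18 and 41 genes differed by limma, and 21 differed with scan day as a block. The sign of the difference from the spotted platform depends on the source of the values. It stayed positive at an offset of 10, with 0.62 and 0.92, and with local background subtracted without an offset, with 0.75 and 1.28 (adjusted exact p 0.0429 for all 4). With that subtraction on the 60-mer arrays alone it was 0.12 and 0.65 and no longer passed the threshold (adjusted exact p 0.657 and 0.0857). With the scanner software's signals on the 60-mer arrays alone it was -1.24 for the transcriptional and -0.85 for the ChIP-capable platform. When background subtraction was also left out on the spotted arrays it was -1.84 and -1.45 (adjusted exact p 0.0429 for all 4), and with the authors' deposited values it was -0.28 and -0.24 (adjusted exact p 0.257 each).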

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

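Among the tests in this part, the one on background left in the 60-mer signals was chosen after its result was seen, as were the bounds for dim genes. The restriction to pSOL1 genes measured on all 3 platforms was added after the data were seen, with its expected outcomes written before its result.

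Values of single arrays stood apart from the other 3 arrays of their platform in 7 of 226 gene and platform groups tested, where chance alone would give about 11.3. On transcriptional array S3 the log2 ratio was 5.02 for ilvB (CAC3169) against a mean of 4.84 on the others, 0.0125 for CAP0143 against -0.15, and -1.88 for pgm (CAC0712) against -2.23. On ChIP-capable arrays, adhE2 (CAP0035) had -5.95 on S2 against -5.34, and CAC0658 had 3.78 on S3 against 3.43. The same held there for CAC1073, with 2.71 on S1 against 3.54, and for the flagellin gene CAC1634, with -2.31 on S4 against -2.48.

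Single named genes also differed between platforms by limma, given here as log2 differences. Between the transcriptional and the ChIP-capable platform they were -1.41 for fhuB (CAC0789), 1.32 for leuB (CAC3171), 2.51 for adhE2 and -1.19 for ctfB (CAP0164). From transcriptional to spotted they were -1.68 for rplK (CAC3148), -1.63 for CAP0066, 1.34 for CAP0067, 1.71 for ctfA (CAP0163) and 1.48 for ctfB. For the chromosome, ChIP-capable minus spotted gave -1.01 for CAC0587, of uncertain size because 1 of its 3 ChIP-capable probes was saturated in ATCC824 on all arrays, 1.87 for fhuB, -1.09 for carA (CAC2645) and -1.69 for rplK. For pSOL1 it gave -1.98 for adhE2, 2.06 for CAP0067, 1.80 for ctfA and 2.67 for ctfB. The M5 levels of these pSOL1 genes on the 60-mer platforms lay near the added offset, and ctfA was well above background in M5 on 2 of 4 ChIP-capable and 1 of 4 spotted arrays, so the sizes are uncertain. The M5 signals of 4 further genes were not well above background on any spotted array, so only a bound exists there. Limma gave 1.57 (transcriptional) and 1.22 (ChIP-capable) for pdc (CAP0025), of which the bound leaves at least 1.08 and 0.733. For the ChIP-capable platform it gave 1.24 for CAP0068 and 1.38 for CAP0091, of which at least 1.08 and 1.01 are left. M5 has no template for these genes, and their 60-mer M5 levels also lay near the added offset (6.43 and 6.00 for pdc). These minimum differences therefore hold for the signals and not for transcripts. For thlR (CAP0079) limma gave -1.58 and -1.38, but the 60-mer values lie beyond the spotted bound, so no difference between platforms is shown. CAC0661 and cbiG (CAC1370) moved in opposite directions, with -1.07 and -1.02 on the spotted platform against 1.96 and 1.07 on the transcriptional platform. Spots of the spotted platform whose names begin with IG, used in no comparison, were above background in both strains on all arrays for 52.0% of spots (53 of 102), against 27.5% (11 of 40) of spots named Alien and 62.4% of gene spots. What the IG spots hold is not given in the sources used here.

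The pSOL1 median lay 0.764 (transcriptional) and 0.926 (ChIP-capable) log2 units above that of the spotted platform. The result does not argue for a real difference in RNA, because the labels describe the mixtures alike on all platforms, apart from the 2 ChIP-capable arrays with a shorter list. Whether the same physical mixtures were used on every platform is not stated in the labels. No biological explanation was tested. Over the 125 pSOL1 genes measured on all platforms the differences were 0.475 and 0.660 (adjusted exact p 0.0857 each), so part of the gap may come from different genes being measured, and how much is left open by the spread between arrays. Background left in the 60-mer signals stays open. The scanner software's signals moved the 60-mer medians to -2.97 and -2.58, below the spotted median of -1.73, with differences of -1.24 and -0.85 (adjusted exact p 0.0429 each). They also carry the software's dye normalization, however, and plain subtraction of local background on all platforms kept the gap at 0.749 and 1.28 (adjusted exact p 0.0429 each), whereas the same subtraction on the 60-mer arrays alone left 0.122 and 0.653 (adjusted exact p 0.657 and 0.0857). The day of scanning remains open as well, because all spotted arrays were scanned on a day of their own.

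Many pSOL1 probes kept signal in the M5 channel of the 60-mer arrays, with 115 and 119 of 178 genes well above background on all 4 arrays. A constant share of ATCC824 RNA in the M5 mixture would give 1 fraction at all brightness levels, but the median M5 fraction in the brightest 45 pSOL1 genes was 0.144 (transcriptional) and 0.124 (ChIP-capable) times that in the next 44, at 0.440% against 3.05% and 0.660% against 5.33%. This argues against carried-over RNA as the main source. Against the negative control spots, 15 and 2 of 178 pSOL1 genes exceeded their 95th percentile in M5 on all 4 arrays. Base composition stays open, since GC content correlated with the M5 signal of pSOL1 probes at rho 0.285 (530 probes) and 0.130 (529 probes) but also with the ATCC824 signal at 0.367 and 0.319, and cross-hybridisation with chromosomal relatives was not tested.

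Between the 60-mer designs 20 genes differed, against 125 and 147 for the comparisons with the spotted platform. Different probe sequences are a candidate explanation, because the SD over 1263 genes of the difference between designs was 0.381 times as large for probes shared by both designs (0.134) as for design-specific probes (0.351), with 3 and 23 genes over 2-fold apart. Without a dye term the 8 arrays of a pair can be split in 35 ways. The real split gave 21, 125 and 147 genes and the highest other 1, 0 and 0. Only 1 of 35 splits reached each real count, the smallest share these splits can give, without adjustment over the 3 comparisons. The other splits put arrays of both platforms in each group, so the platform difference widens their spread and holds their counts down. The splits therefore cannot exclude chance. No biological explanation was tested.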

How the results depend on the processing

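Tests with pSOL1 genes measured on all 3 platforms, the permutation tests with an offset of 10, with the deposited values and with single arrays left out, the counts without the 2 ChIP-capable arrays with a shorter list of samples, the brightest probe for the counts between platforms, the scanner software's signals on the 60-mer arrays alone, local background subtracted without an offset, dim genes at their bound, and the ribosomal list without members annotated as other proteins were chosen after the data were seen.

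Leaving out any single array moved no count by over 1.5 times, no median by more than its spread and no platform difference across its threshold where a test could reach it. Chromosomal calls then ranged from 310 to 346 higher and 189 to 209 lower on the transcriptional, 281 to 302 and 177 to 189 on the ChIP-capable, and 366 to 385 and 210 to 221 on the spotted platform. The loess curve fitted on chromosomal spots left every result within its spread, and limma's test against array spread left the counts as they were. Without the 2 ChIP-capable arrays whose M5 mixture lists fewer samples, that platform gave 294 higher and 177 lower genes and a pSOL1 median of -0.72. The array number was not a pairing, since deviations of same-numbered arrays from their platform means correlated at -0.23 to 0.39, with 0.09 to 0.28 between the transcriptional and the spotted platform (0.16 to 0.40 for them with dye orientation removed, and -0.31 to 0.05 for the other pairs), and not every array correlated best with its own number. As a replicate block it gave 21, 124 and 147 genes differing between platforms, against 20, 125 and 147 without the block. Scan day as a block gave 21 genes between the 60-mer platforms. Among the 80 named genes, 237 values moved by more than their spread over all alternatives and 1283 did not, and 0 called genes changed sign. Genes with 1 strain not well above background on any array of a platform were also set to their bound, which left every result within its spread, with a spotted pSOL1 median of -1.67 and differences from it of 0.71 and 0.87 (adjusted exact p 0.0429 each). Without 4 members annotated as other proteins the ribosomal list's median stayed at 1.04. Signal over background limits the pSOL1 values, since many had M5 signals near background and their medians moved with the offset.

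With the scanner software's signals on the 60-mer arrays and no subtraction on the spotted arrays, 563 genes were higher and 322 lower on the transcriptional and 557 and 318 on the ChIP-capable platform, whereas the spotted platform gave 284 and 172. The pSOL1 medians became -2.97, -2.58 and -1.12 on the transcriptional, ChIP-capable and spotted platforms, so the differences from the spotted platform reversed to -1.84 and -1.45. This alternative changed the background term on all platforms and the dye normalization on the 60-mer platforms. With the scanner software's signals on the 60-mer arrays alone and the spotted arrays as before, the differences reversed to -1.24 and -0.85 (adjusted exact p 0.0429 each), so the reversal does not need the change on the spotted arrays. Correlations with the spotted platform fell to 0.853 for both 60-mer platforms, and 47, 344 and 315 genes differed between platforms. List medians that moved were -7.43 (solvent formation), -2.23 (all pSOL1 genes), -0.0903 (pyruvate oxidation), -0.30 (flagella) and -0.78 (histidine). Further list medians were 0.15 (tryptophan), 0.36 (cellulosome), -0.25 (prophage) and -0.39 (sugar phosphotransferases).

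At an offset of 10 the pSOL1 medians were -1.67, -1.37 and -2.29, and the differences from the spotted platform were 0.62 and 0.92 (adjusted exact p 0.0429 each). The list medians that moved were -6.87 (solvent formation), -1.68 (all pSOL1 genes), -0.14 (sporulation), -0.25 (flagella) and 3.65 (purine). The rest were 2.95 (pyrimidine), -0.65 (histidine), 4.89 (branched-chain), 0.19 (cellulosome) and -0.33 (sugar phosphotransferases). A smaller offset pulls dim ratios less towards 0 by construction. With local background subtracted without an offset and the loess curve as before, the pSOL1 medians were -1.61, -1.08 and -2.36, and the differences from the spotted platform stayed at 0.75 and 1.28 (adjusted exact p 0.0429 each). With this subtraction on the 60-mer arrays alone the differences were 0.12 and 0.65 and no longer passed the threshold (adjusted exact p 0.657 and 0.0857), since only the 60-mer ratios were then freed from the offset.

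Centring arrays on their medians gave 516 higher and 121 lower genes on the transcriptional and 464 and 110 on the ChIP-capable platform. The ChIP-capable pSOL1 median became -0.92, and r became 0.975 between the 60-mer platforms and 0.896 between the ChIP-capable and the spotted platform. Its list medians were 0.25 (acid formation), -0.50 (glycolysis), 0.36 (pyruvate oxidation), 0.88 (heat shock), -0.16 (sporulation), 1.55 (ribosomal proteins), 0.45 (tRNA synthetases) and 0.98 (ATP synthase). They were also 3.83 (purine), 2.73 (pyrimidine), -0.14 (tryptophan), 4.74 (branched-chain), 0.0088 (cellulosome), -0.038 (prophage), -0.30 (sugar phosphotransferases) and 0.052 (iron transport). The iron transport median thereby changed sign, and the cause was not tested.

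The deposited values gave 511 higher and 333 lower genes on the transcriptional, 504 and 350 on the ChIP-capable and 344 lower genes on the spotted platform. The pSOL1 medians were -2.55, -2.51 and -2.27, so the differences from the spotted platform reversed to -0.28 and -0.24 (adjusted exact p 0.257 each, against 0.0429 in the main processing). Correlations with the spotted platform were 0.874 and 0.869. The lists had medians of -8.12 (solvent formation), -2.30 (all pSOL1 genes), -0.30 (acid formation), 0.37 (pyruvate oxidation), -0.17 (sporulation), -0.36 (flagella) and 3.73 (purine). Other lists had 2.91 (pyrimidine), -0.89 (histidine), 5.01 (branched-chain), 0.24 (cellulosome), -0.33 (prophage) and -0.54 (sugar phosphotransferases). The cause was not tested, since the authors' normalization is not given in the sources used here.

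With the brightest probe of each gene the 60-mer pSOL1 medians were -1.17 and -0.99, and r was 0.958 between the 60-mer platforms, 0.884 from transcriptional to spotted and 0.873 from ChIP-capable to spotted. Lists moved to -6.20 (solvent formation), -1.27 (all pSOL1 genes), -1.204 (glycolysis), 0.27 (heat shock), -0.13 (sporulation), -0.23 (flagella) and 0.91 (ribosomal proteins). They also moved to 0.11 (tRNA synthetases), 0.32 (ATP synthase), 2.73 (pyrimidine), -0.55 (histidine), 0.063 (cellulosome) and -0.25 (prophage). Without the filter on dim genes the spotted pSOL1 median was -1.40, the correlations with the spotted platform were 0.897 and 0.882, and the list medians that moved were -0.046 (sporulation), -0.094 (tryptophan) and 4.20 (branched-chain). The cause was not tested for either.

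The calls depend on the threshold by construction. At 1.5-fold there were 667 higher and 454 lower genes on the transcriptional, 624 and 403 on the ChIP-capable and 695 and 515 on the spotted platform. At 3-fold there were 121 and 78, 110 and 60, and 147 and 78. Without a minimum difference, limma's adjusted p alone counted 629, 1685 and 1920 genes between platforms. Spearman's rho was 0.950, 0.864 and 0.840, and r over chromosomal genes alone was 0.888 and 0.871 against the spotted platform. Over the 125 pSOL1 genes measured on all platforms, the 60-mer medians were -1.33 and -1.15, and the differences from the spotted platform of 0.48 and 0.66 no longer passed the threshold (adjusted exact p 0.0857 each), with fewer genes in each median.

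Single platforms gave other list medians, partly because they measured other members. The transcriptional platform alone gave -0.43 (acid formation), -0.057 (pyruvate oxidation), -0.036 (sporulation) and 2.81 (purine). From the ChIP-capable platform alone they were -5.27 (solvent formation), -0.81 (all pSOL1 genes), -0.28 (acid formation), -0.91 (glycolysis), -0.31 (pyruvate oxidation), 0.19 (heat shock) and -0.012 (sporulation). It also gave -0.13 (flagella), 0.24 (tRNA synthetases), 2.85 (purine), 2.14 (pyrimidine), 0.094 (tryptophan), 3.60 (branched-chain) and -0.995 (iron transport). On the spotted platform alone they were -6.98 (solvent formation), -1.72 (all pSOL1 genes), -0.51 (acid formation), -1.17 (glycolysis), 1.17 (pyruvate oxidation), -0.14 (sporulation), -0.30 (flagella) and 0.90 (ribosomal proteins). Also there were 0.11 (tRNA synthetases), 0.27 (ATP synthase), 3.07 (purine), 2.99 (pyrimidine), -0.11 (histidine), -0.40 (sugar phosphotransferases) and -0.17 (iron transport). The cause was not tested.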

Other observations

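Both tests of gene neighbourhood in this part were chosen after the pattern was seen, and the genes named here were chosen after their values were seen.

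Several groups of adjacent genes that the lists covered little or not at all were called alike on every platform that measured them. The longest ran over 23 loci from CAC1996 to CAC2018, all higher in M5, with a mean log2 ratio of 1.85 and members from 1.25 to 2.74. Its annotations include siderophore or surfactin synthetase relatives (CAC2004 at 1.68, CAC2005 at 1.59), the ketoacyl synthase genes pksF (CAC2008 at 1.90) and fabH (CAC2011 at 1.96), glycosyltransferases and an ABC transporter ATPase (CAC1998 at 2.74). The 11 genes from CAC3622 to CAC3632 were higher, with a mean of 1.84. They hold the oligopeptide transporter genes oppF (1.96), oppD (2.02), oppC (1.71), oppB (1.82) and oppA (1.21), and pterin enzymes such as CAC3624 (2.10). The 9 genes from CAC1798 to CAC1806, with nusA (1.72), infB (1.60) and truB (1.71), had a mean of 1.58. The 6 genes from CAC0662 to CAC0667, of which 5 are annotated as sugar-binding proteins or sugar transporter components, had a mean of 2.16 and ran from 1.72 to 2.97, and the 5 genes from CAC0892 to CAC0896, annotated with steps of aromatic amino acid synthesis (aroB at 1.86, aroA at 1.72, aroC at 1.57), a mean of 1.84.

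Among decreases outside the lists, the 6 genes from CAC0590 to CAC0595 had a mean log2 ratio of -2.47. They include the riboflavin synthesis genes ribD (CAC0590) at -2.81 and ribB (CAC0591) at -2.57, and lie close to CAC0587 and CAC0588, the lowest chromosomal genes.

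Ratios of neighbouring loci were alike in general. The correlation of log2 ratios across pairs of chromosomal loci was 0.610 for adjacent loci (3586 pairs), 0.434 at 2 loci apart, 0.252 at 5, 0.166 at 10 and 0.0244 at 50. Of the 391 called chromosomal genes, 243 higher and 148 lower, 187 pairs were adjacent and called in the same direction. Random placements of the calls gave a mean of 21.5 such pairs and at most 39 in 10000 draws (permutation p = 1e-04, the smallest these draws can give). There were 29 runs of at least 3 genes, holding 168 genes, and 14 runs of at least 5. Operons were not annotated in the files, so whether these runs are transcription units was not tested.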
